A study of Mus musculus with 6 samples.

How the data were processed

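Total RNA from pre-B cells of E17.5 mouse embryos was measured on 6 arrays of the Illumina MouseWG-6 v2 type, on which every transcript is read by beads that carry an oligonucleotide probe. Per the labels, all embryos carried the Eµ-Myc transgene, which drives the Myc oncogene in B lineage cells, on a C57BL/6 background. The cells of 3 samples were wildtype for Smchd1 and those of 3 samples were homozygous for a gene trap allele of it. The labels describe purification by cell sorting, RNA extraction with a column kit and synthesis of biotinylated cRNA. They do not name the organ or the sorting gate, and they do not say whether each array holds a separate embryo, so p-values measure the spread between these samples.

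The deposited intensity values are mean bead intensities per probe on a linear scale, exported by GenomeStudio 1.8.0 with no normalization, per the file headers. The submitters' processing notes name BeadStudio, limma 3.12.1 and R 2.15.1. The deposited p-value columns are detection p-values, the share of negative control probes at least as bright as the probe, and one of the deposited tables holds 1 minus that p-value instead. The authors' normalized values are on the log2 scale and were made with normexp background correction from control probes followed by quantile normalization (neqc), per the deposited description of the commands. These log2 values had a median of 4.78 on each array and differed from those computed here by at most 5e-09, so their scale is settled and no centring was applied.

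The deposited intensities of 45281 probes and of 974 control probes, 936 of them negative controls, were background corrected, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16. A probe entered the tests when its detection p was under 0.05 on at least 3 of the 6 arrays, which left 15878 probes. Control probes were left out after normalization. The symbols in the probe table follow the array's design. They were matched to RefSeq genes (assembly GRCm38.p6), 27400 probes by the current symbol and 8341 by a synonym that belongs to 1 gene, and 9540 probes kept the name in the file, so that 78.9% of the probes were matched. The array tables used here name no genome build, and the reference table was used only for names, for the chromosome of a gene and for the order of neighbouring genes.

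Smchd1 null was compared with wildtype by limma's linear model with empirical Bayes moderation (lmFit and eBayes), 3 arrays against 3, two-sided, without a covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene was represented by its detected probe with the highest mean level over the 6 arrays, which gave 10904 genes. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over 19 lists, and again with an estimated correlation. Members past the threshold were counted after adjustment over all probes and after adjustment over the list alone. The lists were clustered protocadherins, imprinted genes, X-linked genes, Hox genes, early B progenitor genes, B lineage identity genes, later B cell genes, Myc targets and ribosome biogenesis, cell cycle, p53 targets and apoptosis, interferon response, heterochromatin and DNA methylation factors, immediate early and stress genes, sex-linked marker genes, and markers of erythroid, myeloid, megakaryocyte and mast, T and NK cells and of hepatocytes. Changed genes were counted per chromosome with Fisher's exact test, two-sided. Where a probe was not detected on any array of a group, the change is given as at least N-fold, the mean of the brighter group over the mean, per array, of the higher of the lowest detected signal and the probe's own signal.

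The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Smchd1, then the 10 genes with the largest change in each direction among those past the threshold whose groups did not overlap. Where fewer than 5 passed in a direction, those with the smallest p were added up to 5 and are given as not past the threshold. In each list it took up to 4 members with the smallest p among those past the threshold over the list alone, or the 2 with the smallest p where none passed. Probes with no symbol or with a clone identifier only were counted and not named. Some genes that the rule takes are not reported here.

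The alternatives were other background corrections, offsets and normalizations, the authors' deposited log2 values, other detection filters, an intensity trend with robust moderation, array weights, the replicate number as a block, the omission of each array in turn, other thresholds, the mean of all detected probes of a gene and an estimated correlation in the list tests. All 6 arrays lay on 1 BeadChip with the genotypes alternating along it, so a slide block could not be fitted. On 20 simulated data sets of 15878 probes, with the means and spreads of these arrays and 200 changed probes each, the comparison of Smchd1 null with wildtype recovered 39.3% of changes of 1 on the log2 scale, 83.9% of changes of 2 and 98.3% of changes of 4, and 3.9% of its calls were false. On 20 simulated data sets of 10904 genes, the list test found a list of 12 genes moved by 1 in 20 of 20 and called 1 of 360 unmoved lists. The noise of each simulated probe or gene was drawn independently, so the rates do not cover genes that move together on an array. The 200 planted changes also make the adjusted threshold easier to pass than with few changes, so the recovered shares can be too high here. Arrays give no counts, and their number limits the precision. Figures were drawn with matplotlib.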

Results

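The series measured gene expression in pre-B cells, precursors of antibody-producing B cells, sorted from E17.5 mouse embryos that carried the Eµ-Myc transgene. It asked which transcripts differ when Smchd1, a chromatin protein with a part in X inactivation and in the silencing of imprinted and clustered genes, is missing. There were 3 wildtype and 3 Smchd1 null arrays. Of the 45281 probes, between 15309 and 16447 were detected per array, and the mean intensity of the negative controls lay between 136.2 and 165.9. Pairs of arrays correlated at r of 0.984 to 0.994 over the tested probes, except that each pair with Smchd1 null replicate 3 lay at 0.946 to 0.956.

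By its brightest probe, Smchd1 itself was high in all wildtype samples and below detection in all null samples. Its brightest probe had a normalized log2 intensity of 9.61 ± 0.09 (SD, n = 3) in wildtype and 4.87 ± 0.21 (SD, n = 3) in Smchd1 null, at least 22.3-fold lower (limma adjusted p = 5.6e-05). The array holds 5 Smchd1 probes. Another probe, detected in all wildtype and in none of the null samples, was at least 4.07-fold lower (adjusted p = 0.00945). One more had a log2 fold change of -1.09 (SE 0.27, adjusted p = 0.86) and stayed above detection in all 3 null samples. The other 2 probes were not detected on any array. The labels do not place the gene trap relative to these probes.

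Loss of Smchd1 was accompanied by a very small set of changed transcripts. The imprinted gene Ndn (necdin), expressed from the paternal chromosome, rose 19.7-fold, and transcripts of plasma proteins that hepatocytes secrete fell. In all, 9 of 15878 probes passed the threshold, 2 higher and 7 lower in Smchd1 null, and these were probes of 8 genes. All 9 changes exceeded 1 on the log2 scale. At an unadjusted p under 0.05 there were 641 probes, 304 higher and 337 lower, which is 4% of those tested. The 2 groups did not overlap for 1526 probes, or 9.6%, where chance gives 10%. Without Smchd1 null replicate 3 the count was 41 probes, 13 higher and 28 lower, and without any 1 of the other arrays it was 2 to 4. Median scaling in place of quantile normalization gave 56 probes, 13 higher and 43 lower, and array weights gave 52. With median scaling the limma adjusted p of Smchd1 fell to 3.44e-23 at a nearly unchanged log2 fold change of -4.80. Array weights counted Smchd1 null replicate 3 at 0.16, against 0.66 to 2.22 for the other arrays.

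**Figure D1:**
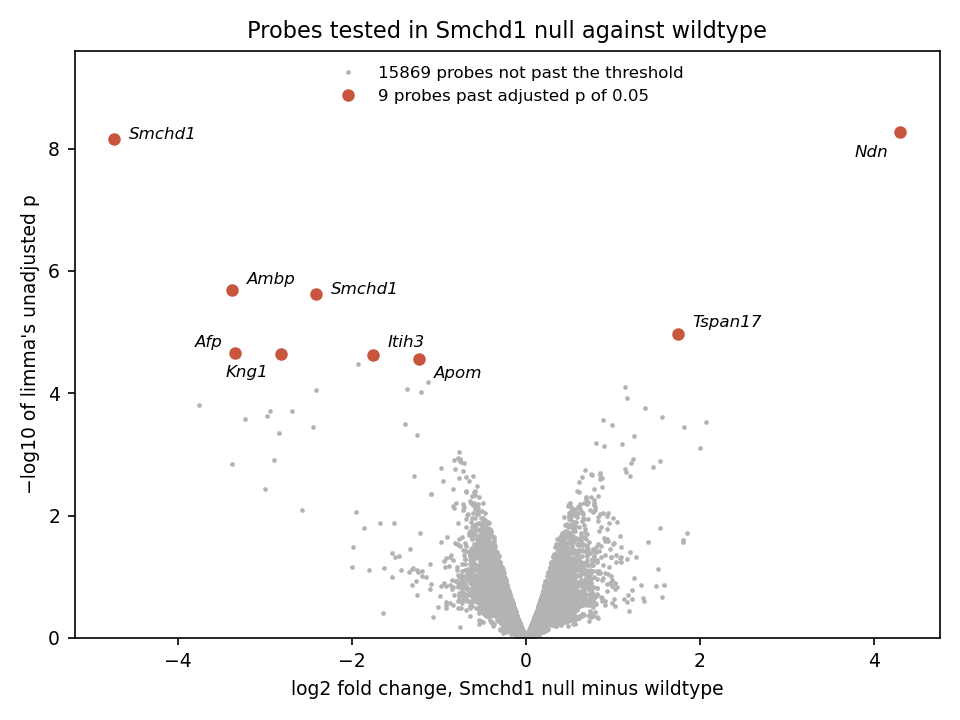
Each point is 1 of the 15878 tested probes, with the log2 fold change of Smchd1 null minus wildtype on the x axis and the negative log10 of limma's unadjusted p on the y axis (3 arrays per group). The 9 probes past an adjusted p of 0.05 are labelled by gene, with Ndn at 4.30 and the brightest Smchd1 probe at -4.73, a fitted difference to a level below detection, apart from all others.

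Ndn had a log2 intensity of 6.55 ± 0.11 (SD, n = 3) in wildtype and 10.85 ± 0.08 (SD, n = 3) in Smchd1 null, a log2 fold change of 4.30 (SE 0.14, adjusted p = 5.6e-05). It passed the threshold under each of the 16 alternatives that refit single probes. Tspan17, which encodes a tetraspanin membrane protein, was the other gene that rose, by 1.75 on the log2 scale (SE 0.16, adjusted p = 0.0338), but its second detected probe had a log2 fold change of 0.19. Its adjusted p lay between 0.104 and 0.347 when any 1 array other than Smchd1 null replicate 3 was left out. The next genes in order of p did not pass. Jun, a subunit of the AP-1 transcription factor, had a log2 fold change of 1.37 (SE 0.20, adjusted p = 0.153). Mkrn3, a paternally expressed neighbour of Ndn on chromosome 7, had 1.56 (SE 0.23, adjusted p = 0.175), and Isl1, a LIM homeodomain factor that was not detected in wildtype, was at least 1.84-fold higher (adjusted p = 0.244). Jun and Mkrn3 were each detected on 1 of the 3 wildtype arrays, and all 3 genes were higher in each null sample than in each wildtype sample. Jun and Mkrn3 passed with median scaling (limma adjusted p of 0.0297 and 0.00857) and with array weights (0.0142 and 0.00151).

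**Figure D2:**
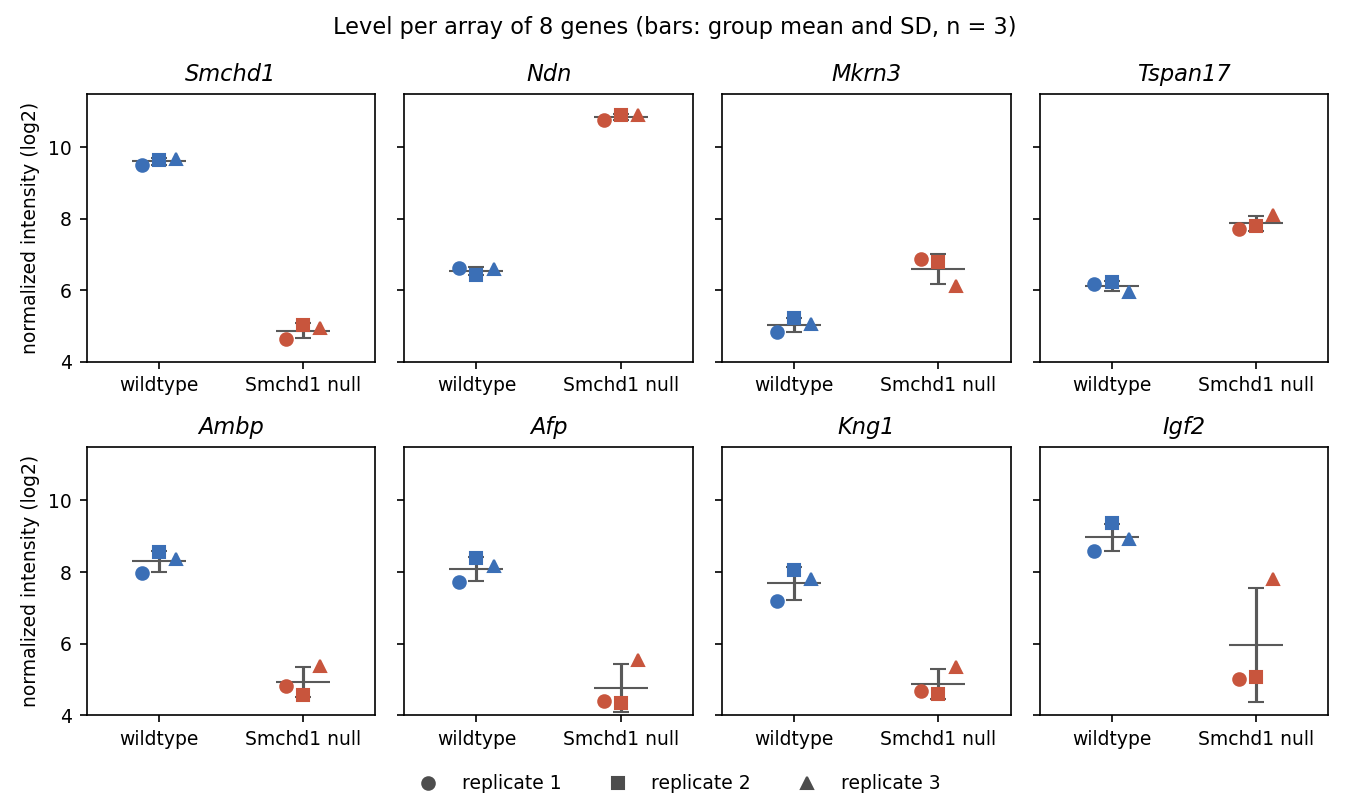
Normalized log2 intensity per array of 8 genes in wildtype (blue) and Smchd1 null (red), with horizontal bars at the group mean and error bars of 1 SD (n = 3), and replicates by symbol. Ndn lies between 6.42 and 6.63 on the wildtype arrays and between 10.76 and 10.90 on the null arrays, and for Igf2 Smchd1 null replicate 3 lies at 7.81 where the other nulls lie at 5.01 and 5.07.

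The 5 genes other than Smchd1 that fell encode secreted proteins of liver and plasma. Ambp, the precursor of alpha-1-microglobulin and bikunin, fell by 3.38 on the log2 scale (SE 0.25, adjusted p = 0.00945). Afp (alpha-fetoprotein) fell by 3.33 (SE 0.35) and Kng1 (kininogen) fell by 2.81 (SE 0.29), both with an adjusted p of 0.0472. These 3 genes were each detected on 1 null array. Itih3, a heavy chain of the inter-alpha-trypsin inhibitor, was at least 2.58-fold lower (adjusted p = 0.0472), and Apom, an apolipoprotein, fell by 1.22 (SE 0.13, adjusted p = 0.049). Apart from Ambp, these calls are close to the threshold. Leaving out any 1 array other than Smchd1 null replicate 3 gave adjusted p-values of 0.0466 to 0.568 for the 5 genes. Without Smchd1 null replicate 3 the adjusted p-values were 0.00106 to 0.0276.

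The list of hepatocyte markers fell as a group. All 12 of its detected members were lower in Smchd1 null, with a median log2 fold change of -2.92, and for 11 of them the groups did not overlap. After adjustment over the list alone 11 passed, and 2, Ambp and Afp, passed over all probes, or 9 members without Smchd1 null replicate 3 and 0 or 1 without any 1 other array. Besides these, Ahsg (fetuin-A) had a log2 fold change of -3.75 (SE 0.53, adjusted p over the list alone of 6e-04) and Apoa1 (apolipoprotein A-I) had -2.94 (SE 0.43, 6e-04), both detected on 1 null array. The camera adjusted p of the list was 8e-26, and the adjusted p was 0.153 with an estimated correlation. Per array, the median of the list relative to the wildtype mean was -3.50, -3.45 and -1.56 in Smchd1 null replicates 1, 2 and 3. Members such as Ahsg, Afp, Ambp and Apoa1 were not detected in replicates 1 and 2. The values of -3.50 and -3.45 are thus differences to background and give no exact size. The median of the myeloid markers was also lower in null replicates 1 and 2, at -1.99 and -1.86, but lay at 0.52 in null replicate 3, above all wildtype arrays, and wildtype replicate 1 was the lowest wildtype array for both lists, at -0.35 for hepatocyte and -0.71 for myeloid markers. The 1 probe for albumin (Alb) was not detected on any array, at log2 intensities of 4.53 to 4.70, where detection began at 5.08 to 5.19.

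**Figure D3:**
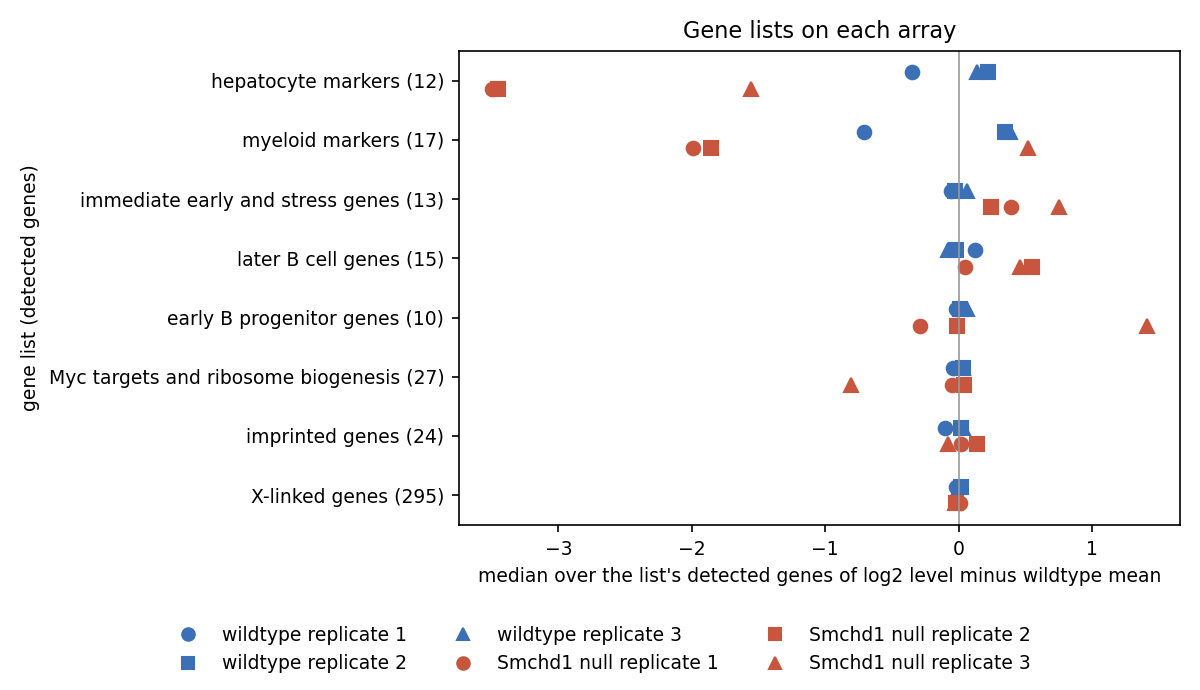
Median over the detected genes of each list of the log2 level minus the gene's wildtype mean, 1 symbol per array, with wildtype in blue and Smchd1 null in red and the number of detected genes in brackets. Hepatocyte markers lie at -1.56 or lower on each null array, and Smchd1 null replicate 3 stands alone at 1.41 for early B progenitor genes and at -0.81 for Myc targets.

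Imprinted genes, clustered protocadherins and X-linked genes are classes that Smchd1 is known to act on, and none of the 3 lists passed the list test. Of 24 detected imprinted genes, 13 were higher and 11 lower, and the camera adjusted p was 0.302. After adjustment over the list alone 3 of them passed, Ndn and Mkrn3 (0.00291) higher and Igf2 lower, and over all probes only Ndn did. Without Smchd1 null replicate 3, 4 passed higher and 3 lower over the list alone, and 3 passed over all probes. None passed lower over the list alone without Smchd1 null replicate 1 or any 1 wildtype array. Igf2, a paternally expressed growth factor that fetal liver also makes, had a log2 fold change of -3.00 (SE 0.71, adjusted p over the list alone of 0.0298) and was detected on 1 null array, with the values of the single null arrays ordered as for the hepatocyte markers. Of the other genes in the Ndn cluster, Snurf had a log2 fold change of -0.19 (SE 0.52), which was 0.47 (SE 0.19) without Smchd1 null replicate 3, and Ube3a had one of -0.48 (SE 0.22), neither past the threshold with or without that array. Magel2 was detected on 1 array and Peg12 on none, so that neither was tested. Only 4 of the 54 clustered protocadherins on the array were detected, 2 higher and 2 lower (adjusted p = 0.84), and the direction of the list turned to higher without Smchd1 null replicate 3 (0.625). Pcdhgc5 had a log2 fold change of -0.30 (SE 0.29), or 0.01 without that array, and Pcdhgb4 one of 0.13 (SE 0.25).

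Of 295 detected X-linked genes, 136 were higher and 159 lower, none passed over all probes or over the list alone, and the adjusted p was 0.94. The smallest p among them belonged to Rbm3, a cold-induced RNA-binding protein, at -0.83 (SE 0.16, adjusted p over the list alone of 0.36), and to Gab3 at 0.57 (SE 0.17). The 4 probes for Xist, the RNA that coats the inactive X chromosome, were not detected on any array. Of the Y-linked genes, Kdm5d was detected on all 6 arrays and Uty on 3 wildtype arrays and 1 null array. No array thus showed a sign of an inactive X chromosome, so the X-linked test cannot show whether Smchd1 loss changes genes on one. Among the sex-linked marker genes 4 were detected, 1 higher and 3 lower (adjusted p = 0.577), with Uty at -0.23 (SE 0.19) and Kdm5d at 0.15 (SE 0.16). Of 5 detected Hox genes 4 were higher and 1 lower (adjusted p = 0.471). Hoxa7 had a log2 fold change of 1.54 (SE 0.49, adjusted p over the list alone of 0.0789) and was higher in all null samples than in all wildtype samples. It had 0.92 (SE 0.18) without Smchd1 null replicate 3, which lay at 8.68 against 6.96 and 6.70 in the other nulls. Over the list alone 1 Hox gene passed, higher, without that array and 1 without Smchd1 null replicate 2. Hoxd11 had one of -0.45 (SE 0.29). The Hox list passed under median scaling, with an adjusted p of 0.0229, and with a detection p under 0.01 on all 6 arrays, with 0.026. With all arrays and an estimated correlation its adjusted p was 0.753.

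Immediate early and stress genes rose as a list in Smchd1 null, with 10 of 13 detected members higher, a median log2 fold change of 0.54 and a camera adjusted p of 5.51e-05, but the adjusted p was 0.153 with an estimated correlation. The median was 0.32 without Smchd1 null replicate 3, where the list stood at 0.75 against 0.39 and 0.24 in the other nulls. Jun alone passed over the list, with an adjusted p of 0.00224, and 2 members passed without Smchd1 null replicate 2 or without replicate 3. Later B cell genes, which mark maturation, were higher in 11 of 15 (median 0.32, adjusted p = 0.0141, and 0.753 as the adjusted p with an estimated correlation). None passed singly with all arrays. Without Smchd1 null replicate 1 the median was 0.55 and 5 passed higher over the list alone, and without replicate 2 the median was 0.14 and 1 passed lower. H2-Ab1, a chain of MHC class II, had a log2 fold change of 0.91 (SE 0.33), and the chemokine receptor gene Ccr7 had -0.97 (SE 0.35). The list had an adjusted p of 0.425 without Smchd1 null replicate 2, 0.077 without the detection filter and 0.0635 with a detection p under 0.01 on all 6 arrays. The 17 detected B lineage identity genes, 12 higher and 5 lower, did not pass as a list (adjusted p = 0.28), with Cd72 at -0.44 (SE 0.17).

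In 2 further lists the call rested on Smchd1 null replicate 3. Early B progenitor genes were higher in 10 of 10 (median 0.42, adjusted p = 0.0155, and 0.753 as the adjusted p with an estimated correlation). Il7r, the receptor for interleukin 7, had a log2 fold change of 0.52 (SE 0.29) and the recombinase gene Rag1 had 0.53 (SE 0.33). Without Smchd1 null replicate 3 they had 0.19 (SE 0.16) and 0.17 (SE 0.21). Without that array the list was lower in Smchd1 null, with a median of -0.15 and an adjusted p of 0.0128, or an adjusted p of 0.513 with an estimated correlation, and 4 members passed lower over the list alone. The median was 0.75 without Smchd1 null replicate 1 and 0.63 without replicate 2. With all arrays the call also ended with array weights (0.921) and without the detection filter (0.113). Myc targets and ribosome biogenesis genes were lower in 25 of 27 (median -0.26, adjusted p = 0.00241, and 0.753 as the adjusted p with an estimated correlation), with Pa2g4 at -0.37 (SE 0.22) and Ccnd2, which encodes cyclin D2, at 0.94 (SE 0.55). Without that array the median was 0.01, the direction turned to higher and the adjusted p was 0.574, and with array weights it also turned, with an adjusted p of 0.973. The median was -0.43 without Smchd1 null replicate 2. Pa2g4 had -0.15 (SE 0.15) and Ccnd2 had 0.42 (SE 0.45) without Smchd1 null replicate 3.

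Genes of the cell cycle, of p53 and apoptosis, of the interferon response and of heterochromatin did not pass as lists. Of 27 cell cycle genes 16 were higher and 11 lower (adjusted p = 0.577, and 0.569 with the direction turned to lower without Smchd1 null replicate 3), with Top2a at 0.30 (SE 0.19), although its probes ran from -0.07 to 0.37, and Ccne2 at -0.38 (SE 0.26). The 16 genes of p53 targets and apoptosis were split 8 to 8 (adjusted p = 0.708), with a median of -0.02, a mean of 0.10 and a test direction of higher. Zmat3 had a log2 fold change of 0.51 (SE 0.24) and Bcl2l11 one of -0.34 (SE 0.17). Of 7 interferon response genes 5 were higher (median 0.23, adjusted p = 0.21, and 0.753 as the adjusted p with an estimated correlation), with Irf9 at 0.49 (SE 0.28) and Stat2 at 0.38 (SE 0.24). The interferon adjusted p was 0.0481 without wildtype replicate 2, and 0.715 with a median of 0 without Smchd1 null replicate 3, the array where the list stood at 0.63 against 0.01 and 0.04 in the other nulls. Of 17 heterochromatin and DNA methylation factors 12 were lower (adjusted p = 0.57), with Dnmt3b at -0.24 (SE 0.14) and 0.13 on its second probe, and Cbx3 at -0.34 (SE 0.21).

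Markers of other blood cells were present in both groups. Hba-a1, an alpha globin gene of red cells, had a log2 intensity of 13.33 ± 0.48 (SD, n = 3) in wildtype and 13.73 ± 1.17 (SD, n = 3) in Smchd1 null. Erythroid markers were lower in 6 of 11 (adjusted p = 0.628), with Epor at -0.41 (SE 0.20). Without Smchd1 null replicate 3 the erythroid list had a direction of lower, with an adjusted p of 0.00523, or 0.718 as the adjusted p with an estimated correlation. That rests on Smchd1 null replicate 1, where the median of the list was -0.95, against 0.07 in replicate 2, and without replicate 1 the direction was higher (adjusted p = 0.119). Myeloid markers were lower in 14 of 17 (median -1.24, adjusted p = 3.17e-04, and 0.753 as the adjusted p with an estimated correlation), and with all arrays none passed singly. Ltf (lactotransferrin) had a log2 fold change of -1.67 (SE 0.51) and Ngp (neutrophilic granule protein) had -1.86 (SE 0.60). The myeloid median per array relative to the wildtype mean was -1.99, -1.86 and 0.52 in Smchd1 null replicates 1, 2 and 3, and -0.71, 0.35 and 0.38 in the wildtype replicates. The myeloid adjusted p was 0.293 without Smchd1 null replicate 1 (median -0.50), 0.116 without replicate 2 (median -0.58) and 2.82e-20 without replicate 3 (median -1.99), the last with an adjusted p of 0.217 with an estimated correlation. Without replicate 3, 13 members passed after adjustment over the list alone, all lower, and 1 over all probes. Of 8 T and NK cell markers 4 were lower (adjusted p = 0.77). Lat lay at -0.56 (SE 0.26) and Cd3g at -0.74 (SE 0.70), or at -0.29 and -0.10 without Smchd1 null replicate 3. Only 2 megakaryocyte and mast cell markers were detected (adjusted p = 0.867), Pf4 at 0.56 (SE 1.00) and Hdc at -0.14 (SE 0.46), and without Smchd1 null replicate 3 both had lower values, with an adjusted p of 0.00118 for the list, or 0.217 as the adjusted p with an estimated correlation.

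The 8 changed genes lay on 7 chromosomes and did not gather on one of them. The smallest p of Fisher's exact test belonged to chromosome 17, with 2 of 473 tested genes (exact p = 0.062, adjusted p of 1), and one of the 2 was Smchd1. With median scaling the smallest adjusted p was 0.0122 and with array weights 0.0221, in both for chromosome 12, with 7 and 6 of 318 tested genes. The test counts related neighbouring genes singly, and which genes gave these calls was not examined.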

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

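The alternatives here were planned. Ndn passed the threshold under each of the 16 that refit single probes, with log2 fold changes of 3.02 to 4.35, and Smchd1 was lower and past it under each of the 15 that kept its probe, the size of its fall being only bounded. All 9 called probes were also called with median scaling, with array weights and without Smchd1 null replicate 3, the settings with the most calls. The last 2 are close to one another, since array weights counted that array at 0.16. The deposited log2 values equal those used here to within 5e-09, so their same 9 probes are no separate check. An offset of 50 gave 9, of which 7 were shared, and the other refits kept 2 to 7 of the 9. The count of changed probes, then higher and lower, was 56, 13 and 43 with median scaling in place of quantile normalization, which moved the median of all probes from -0.019 to -0.179, and 52, 17 and 35 with array weights. It was 5, 2 and 3 with normexp without control probes and with an offset of 50, 3, 1 and 2 without background correction, 6, 2 and 4 without the detection filter, 14, 3 and 11 at a threshold of 0.1, and 2, 2 and 0 with a stricter filter, a detection p under 0.01 on all 6 arrays, which changes the p and the number of arrays together and leaves out Smchd1 and most hepatocyte markers. Leaving out 1 array gave 2 to 41 changed, 1 to 13 higher and 1 to 28 lower probes, with the highest without Smchd1 null replicate 3. Median scaling gave far lower p-values at changes of similar size. Igf2 had -3.11 with a limma adjusted p of 6.54e-10, against -3.00 with 0.794 after quantile normalization. Calls that median scaling added for such genes thus came from smaller estimates of error and hardly from larger changes.

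With the replicate number as a block, 2 probes passed, 1 higher and 1 lower. Deviations of same-numbered arrays from their group means correlated at 0.02, 0.04 and -0.01, and numbers 1 and 2 but not 3 matched their own number best. With 3 arrays per group, and Smchd1 null replicate 3 apart from the others, these values cannot settle whether the numbers mark pairs.

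The X-linked list turned to higher with adjusted p-values of 0.826 with the mean of all detected probes of a gene, 0.956 without background correction, 0.964 with that normexp, 0.986 with median scaling, 0.938 with the strict filter, 0.987 with an intensity trend and robust moderation and 0.973 with the block, and ran from 0.715 to 0.962 when 1 array was left out. The protocadherin list turned to higher at 0.99 with median scaling and 0.952 without the detection filter, and ran from 0.259 to 0.897. No such value passed the threshold. The test by chromosome passed with median scaling (0.0122) and array weights (0.0221), both for chromosome 12. With the settings of the main comparison 0 genes of that chromosome were called, so both results count genes that these settings added.

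Array weights reversed Cd3g (0.46), Pf4 (-0.46) and the lists of cell cycle (0.527), megakaryocyte and mast cell markers (0.181), Myc targets (0.973) and T and NK cell markers (0.721). Smchd1 null replicate 3 had a weight of 0.16 there, against 0.66 to 2.22 for the other arrays, so this setting nearly leaves it out. Pf4 and the lists of cell cycle, megakaryocyte and mast cell markers and Myc targets also turned without that array. Cd3g and the T and NK list did not. Median scaling reversed the cell cycle list (0.823), the strict filter p53 targets (0.717), no detection filter T and NK markers (0.989), and no background correction Hdc (0). Over the arrays left out in turn, directions also turned within adjusted p ranges of 0.244 to 0.955 (T and NK), 0.00523 to 0.981 (erythroid), 0.291 to 0.955 (cell cycle), 7.28e-04 to 0.0379 (early B progenitor), 0.00118 to 0.981 (megakaryocyte and mast) and 1.91e-06 to 0.574 (Myc targets), and log2 ranges of -0.05 to 0.37 (Pcdhgb4), -0.71 to 0.19 (Hdc), -0.54 to 0.01 (Pcdhgc5) and -0.76 to 1.26 (Pf4). The cause was not tested for any of these unless stated. Among the named genes, Jun, Mkrn3, Igf2, Ahsg, Apoa1, Ltf and Ngp gained a call both with median scaling and with array weights. Hoxa7 gained one only with median scaling and Rbm3 only with array weights. The strict filter left too few clustered protocadherins, hepatocyte markers and megakaryocyte and mast cell markers to test. Bead signal over background limits what is seen of dim genes, since a change below detection is only bounded.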

Other observations

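All tests in this part were chosen after the results were seen. Genes named here beyond the rule for named genes were chosen after their values were seen.

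Without Smchd1 null replicate 3, 29 genes passed the threshold by their brightest probe, 11 higher and 18 lower in Smchd1 null, 5 of them known only by a clone or unmatched name. Of the 17 lower genes with a name, 9 were in the hepatocyte list, Ahsg, Ttr, Serpina1b and Trf among them. Outside the list were Kng1, Itih3 and Apom, which also encode secreted proteins of liver and plasma. So were Serpina1c and Serpina1d, of the same gene family as Serpina1b, and Smchd1, Igf2 and Lyz1. Igf2, not detected in null replicates 1 and 2, was at least 14.1-fold lower (limma adjusted p = 0.00106). The lysozyme gene Lyz1 fell by 2.59 on the log2 scale (SE 0.33, adjusted p = 0.0451), but in Smchd1 null replicate 3 it lay at 10.89, above all wildtype arrays. Higher were Gpc1, a cell surface proteoglycan, by 1.83 (SE 0.14, adjusted p = 0.00404), the imprinted gene Mkrn3, detected on 1 wildtype array, 3.48-fold (adjusted p = 0.00616), and Ube2e2, which encodes a ubiquitin-conjugating enzyme and was not detected in wildtype, at least 1.62-fold (adjusted p = 0.0451). Among immediate early genes, Fos was detected in all 3 null samples and in no wildtype sample. Over all 6 arrays it was at least 2.78-fold higher, with an adjusted p of 0.934. Egr1, of the same list, lay at 5.85 and 6.03 in null replicates 1 and 2, below the wildtype arrays at 6.28 to 6.55. In null replicate 3 it lay at 9.08.

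The 9 changed probes were set against other groupings of the arrays. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called 9 probes, and the highest of the other splits called 0. With 10 splits no share under 0.1 can be had.

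Hepatocyte transcripts were lower in Smchd1 null, and normalization and background correction are argued against as the cause, since the median of the list lay at -1.29 or lower under 5 ways of normalizing. RNA of residual hepatocytes in the wildtype samples stays open, although the cells were purified by sorting: all 12 detected members were higher in wildtype replicate 2 than in wildtype replicate 1, by a median of 0.58, which shared regulation within the cells would also give, and the 9 detected in Smchd1 null replicate 3 lay -2.92 to -0.68 from their wildtype means there, where 1 source would lower all alike down to the background. The myeloid markers moved with the list in null replicates 1 and 2, at -1.99 and -1.86, but not in null replicate 3, at 0.52 against -1.56 for hepatocyte markers. How many of the 17 listed genes, 0 of which are in another list, pre-B cells also express was not measured. While Ttr and Ahsg had mean log2 intensities of 9.31 and 9.04 in wildtype, the albumin probe was at background on every array. It is the only albumin probe, and these arrays do not show that it works, so its level cannot decide the question. An effect of Smchd1 loss on these genes within the sorted cells was not tested and stays open.

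Smchd1 null replicate 3 stands apart, with 1079 of 10904 genes outside the range of the other 5 arrays and at least 1 from their mean on the log2 scale, against 23 to 129 for the other arrays. A mislabelled wildtype sample is argued against by its Smchd1 and Ndn levels. Its brightest Smchd1 probe was below detection, at a log2 difference of -4.65 to the wildtype mean, and Ndn lay at 10.90. Another Smchd1 probe was detected there, at 5.43, below all wildtype arrays. An admixture of myeloid cells alone is argued against by the early B progenitor genes. Of these 10 of 10 lay above all other arrays, Igll1 at 14.56 and Vpreb1 at 13.95 among them. But 9 of 17 myeloid markers lay above all other arrays too, Mpo at 12.06 against 5.05 to 9.83, while Ltf and Camp did not. The 2 detected megakaryocyte and mast cell markers also had a median of 2.11 relative to the wildtype mean on this array. Myeloid cells alongside another difference thus stay open. Lower Myc output in this sample is a candidate explanation, since Myc lay at 6.24 against 8.32 to 8.82 and 25 of 27 detected Myc targets lay below all other arrays, against 35.4% of all genes. Cdkn1a lay at 9.19 against 4.96 to 5.80 and Igkc, the kappa light chain, at 10.96 against 13.40 to 13.76. A sample with more early B cells would also move these lists and stays open, and the labels do not give the B cell stage or transgene dose of each embryo.

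Genes next to Smchd1 on chromosome 17 held small p-values. Of its 40 nearest tested genes in order, 20 on each side, 7 had an unadjusted p under 0.05, and a share of 0.0086 of 8242 overlapping windows of the same size held as many, with a median of 1. With 1 array left out the count was 3 to 9 and the share 0.009 to 0.059, above 0.05 without Smchd1 null replicate 1 (0.057), wildtype replicate 2 (0.059) or wildtype replicate 3 (0.051), so that an effect spread over the neighbourhood, from DNA flanking the trapped allele or in cis, stays open. A sequence variant under the probes of Lbh is argued against, because a mismatch lowers the signal and both Lbh probes were higher in Smchd1 null, by 1.08 and 2.07, or 0.64 and 1.69 without Smchd1 null replicate 3. For the clone-named C030034I22Rik, with -1.93 on one probe and 0.30 on the other, a variant or another transcript form stays open.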
